A study of Homo sapiens with 12 samples.

How the data were processed

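Gene expression was measured on 12 2-colour arrays of 70-base oligonucleotides. Per the labels, 6 arrays compared HTI-286 with vehicle and 6 compared docetaxel with vehicle, as 3 replicates per drug with a dye exchange of each. The deposited table holds log2 ratios, which the authors made by spot quantification in Imagene 5.6 and by background correction and LOWESS normalization in GeneSpring 6.1, per the submitters' processing notes. The base of the log and the sign of the ratios are not given in the sources used here. Log2 was taken from the lowest value of -6.64, the log2 of a linear ratio of 0.01. The median of each array lay between -0.03 and 0.06 over all 23232 rows, and any centring beyond LOWESS is unknown.

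Of these rows, 33 sets of at least 16 carried identical values on all arrays. The 21 sets with no listed gene (1711 rows) were removed, and the 12 sets with a gene were each reduced to 1 row, which left 21329. Gene symbols came from the platform annotation given for the probes, matched by Entrez identifier (17012 rows) to a RefSeq gene table of GRCh38.p14 used for names only, which changed 0 symbols. Of all 23232 rows, 17033 had 1 symbol, 243 had several and 5956 had no listed gene. Of the 21329 rows kept, 16857 had 1 symbol and 4472 had none or several. Probes of 1 symbol were averaged, and probes with none or several stayed single under their identifier. A feature was tested when each of the 6 replicates had a value on at least 1 array, which kept 18900, of them 14665 with a symbol.

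The ratios were used as deposited, with no array's sign turned, and the 2 arrays of a dye-exchanged pair were averaged to 1 replicate. limma 3.58.1 in R 4.3.3 (lmFit and eBayes) was fitted to the 6 replicates with a mean per drug, leaving 4 residual and 1.57 prior degrees of freedom. The contrasts were each drug against 0 and HTI-286 minus docetaxel, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. 30 gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry beside it, adjusted over the 30 lists of a comparison. The lists described are p53 targets, DNA replication and G1/S, heat shock proteins, G2/M and mitosis, tubulins, and markers of leukocytes and of fibroblast and stromal cells. The groups, tests, lists, rule for named genes and first set of alternative settings were fixed before the data were examined.

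The rule for named genes took, per drug, up to 8 genes with a symbol per direction past the threshold, provided the 3 replicates shared a sign. If none passed, it took the 5 with the smallest p in each direction, without that condition. It added the 2 members with the smallest p of each list that passed or held a passing member, shown for both drugs. A fixed set of genes was named in any case, of which 1 is not reported here. For the difference it took up to 5 features each way past the threshold.

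The alternative settings in that first set were centring and scaling of arrays, single probes, stricter and looser filters on missing values, agreement of dye-exchanged arrays, a fit to all 12 arrays with the pair as a random block (duplicateCorrelation, statmod 1.5.0) and a dye term, each dye orientation alone, robust eBayes, limited ratios, a fit per drug, an unmoderated statistic, a replicate block, and leaving out each replicate. The correlation within pairs was -0.0396, so that fit treats the arrays almost as independent. Chosen after seeing the data were lowest values set to missing, only genes above the lowest value on all 12 arrays, that filter with the fit to all arrays, camera on ranks, and the signs of the dye-exchanged arrays turned.

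The procedure was tested on simulated data with known changes among 18900 features, first run after an initial pass over the deposited values. At 4-fold it called 43.9% of changed genes for HTI-286, 37.9% for docetaxel and 26.5% for the difference, and at 2-fold 3.03%, 7.46% and 0%. At 1.5-fold it called none. False calls numbered 7, 1 and 5. A shift of 0.3 in the p53 targets was called for both drugs by camera with the preset correlation, with 0 other lists. The simulated features were drawn independently, with no correlation between genes and no dye effect. The simulation therefore does not show how the list test behaves on the deposited values. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.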

Results

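LNCaP, an established line of human prostate carcinoma cells that respond to androgen, was treated with HTI-286 at 0.75 nM, with docetaxel at 3 nM, or with vehicle, each for a period of 72 h. HTI-286 is an antimicrotubule agent that inhibits tubulin polymerisation, and docetaxel stabilises microtubules. RNA of treated cells and RNA of their vehicle control were compared on the same 2-colour oligonucleotide array. Each drug had 3 replicates, described by the submitters as biological and grown from cells of the same passage, and each replicate was hybridised on 2 arrays with the dyes exchanged, which gave 6 arrays per drug and 12 in all. The sample titles speak of prostate cancer refractory to docetaxel, whereas the protocols describe LNCaP, and whether these cells were refractory is not given in the sources used here. The limma p-values measure the spread between cultures of one line. Camera with a preset correlation compares the members of a list with all other genes, so its p-values do not measure that spread. After repeated rows were removed, the arrays held between 20043 and 21109 values, of which 118 to 726 per array stood at the lowest value in the table, a log2 ratio of -6.64. The number of arrays limits the precision, and no spot brightness was used here.

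The deposited table does not state the direction of its ratios. Drug over vehicle is likely, because the treated RNA is channel 1 of every sample and the submitters describe treatment set against vehicle. Whether the ratios of the dye-exchanged arrays were turned before deposit is not settled, so values of the lists that passed for a drug and of several named genes are also given separately for arrays with the treated RNA in Cy3 and for arrays with it in Cy5. "Higher" and "lower" below mean relative to vehicle under that likely direction.

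The first comparison asked which genes differed between HTI-286 and vehicle. Targets of p53, the transcription factor that responds to DNA damage and other stress, rose as a group by camera with a preset correlation (adjusted p = 2.12e-06), but not with an estimated correlation (adjusted p = 0.232). Of 26 measured members 20 were higher, with a median log2 ratio of 0.28. Genes of DNA replication and the G1/S transition fell as a group by camera (adjusted p = 9.65e-06), but not with an estimated correlation (adjusted p = 0.371), with 26 of 35 measured members lower and a median of -0.23. Among the p53 targets, CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, stood at 1.16 ± 0.32 (SD, n = 3), 2.23-fold, and was above 0 on 6 of 6 arrays. DDB2, a DNA damage recognition protein, stood at 0.71 ± 0.06 (SD, n = 3). Its dye-exchanged arrays differed more than this SD, with -0.14 on Cy3 and 1.59 on Cy5 in replicate 3. With the signs of the Cy5 arrays turned DDB2 stood at -0.20. Among the replication genes, MCM6, a subunit of the replicative helicase, stood at -1.23 ± 0.38 (SD, n = 3), and FEN1, the flap endonuclease, stood at -0.76 ± 0.22 (SD, n = 3). Both were below 0 on 6 of 6 arrays.

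Over all alternatives the adjusted p with HTI-286 ranged from 1.92e-07 to 0.957 for the p53 targets and from 4.09e-06 to 0.856 for the replication genes. With the signs of the arrays with treated RNA in Cy5 turned, an alternative chosen after seeing the data, no list passed camera for either drug. On arrays with the treated RNA in Cy3 the mean of the array medians of the p53 targets was 0.28 ± 0.07 (SD, n = 3), and with it in Cy5 it was 0.32 ± 0.17 (SD, n = 3). The replication genes stood at -0.21 ± 0.09 and -0.25 ± 0.09 (SD, n = 3) on the same groups of arrays. Over all genes tested no p53 target passed, and 3 passed when adjusted over the list alone. These were CDKN1A, DDB2 and RRM2B, a subunit of ribonucleotide reductase, and RRM2B was named after its values were seen. No replication gene passed over all genes or adjusted over the list alone. The G2/M and mitosis genes had a median of -0.09, with 25 of 37 lower (camera adjusted p = 0.423), and 0 passed over all genes or adjusted over the list alone. The tubulins had a median of -0.06 over 12 members (camera adjusted p = 0.773), and the heat shock proteins a median of 0.04 over 20 members (camera adjusted p = 0.169). In fry's test for changes in either direction the tubulins passed (adjusted p = 0.0035), with 1 higher and 2 lower at an unadjusted p under 0.05. Unrelated lists passed that test too, such as fatty acid synthesis (adjusted p = 0.0027), so it does not single out the tubulins. No tubulin passed over all genes or adjusted over the list alone. Markers of other cell types, measured beside these groups, had a median of 0.01 for leukocytes (camera adjusted p = 0.906) and -0.05 for fibroblast and stromal cells (camera adjusted p = 0.867).

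No single gene passed the limma test for HTI-286: 0 of 18900 had an adjusted p under 0.05, the smallest adjusted p was 0.139, and 952 had an unadjusted p under 0.05, where chance gives 945. The limma fit to single arrays, with the dye-exchanged pair as a random block, called 1 gene, CDKN1A (adjusted p = 0.0304), and an unmoderated t statistic called 0. The fit to single arrays counts the 2 arrays of the same RNAs almost as independent. In the limma fit to replicates CDKN1A had an adjusted p of 0.678. With the ratios as deposited, the 5 named genes with the smallest p among those that were higher were CLU, TRPC5, WDR19, ATP6V1E1 and CDKN1A. With the signs of the Cy5 arrays turned these stood at -0.15, 1.54, -0.06, 0.75 and 0.21, so the choice of these genes depends on that direction. Clusterin (CLU), a secreted chaperone, stood at 1.16 ± 0.09 (SD, n = 3). WDR19, which acts in intraflagellar transport, stood at 1.47 ± 0.19, and ATP6V1E1, a subunit of the vacuolar proton pump, at 1.19 ± 0.24 (SD, n = 3). For ATP6V1E1, replicate 1 rests on the Cy3 array alone, and replicate 3 had 2.63 on its Cy3 array and -0.65 on its Cy5 array. The cation channel gene TRPC5 stood at 1.46 ± 0.13 (SD, n = 3), but replicates 1 and 2 rest on the Cy3 array alone, and replicate 3 had 3.17 on its Cy3 array and -0.24 on its Cy5 array. On Cy3 and Cy5 arrays the means were 1.36 and 0.95 for CDKN1A, 1.02 and 1.31 for CLU, and 1.57 and 0.66 for ATP6V1E1. Among those that were lower, the inflammasome sensor NLRP3 stood at -1.14 ± 0.18 (SD, n = 3), with means of -1.66 on Cy3 and -0.63 on Cy5 arrays, and replicate 1 had -2.72 and 0.85. The other 4 were CCDC15 at -3.54, JADE1 at -5.65, RBM28 at -1.93 and FERMT3 at -2.66. These 4 rest on values at the lowest ratio of the table, for RBM28 in single probes of the gene: with such values set to missing, CCDC15 stood at -1.53, RBM28 at -0.31 and FERMT3 at -0.28, and JADE1, measured on Cy3 arrays alone, could not be tested. With the signs of the Cy5 arrays turned, NLRP3 stood at -0.51, CCDC15 at 1.50, RBM28 at 0.53 and FERMT3 at -1.08, while JADE1 kept -5.65. The choice of the lower genes thus depends on that direction too.

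The second comparison asked which genes differed between docetaxel and vehicle. The p53 targets rose as a group by camera here too (adjusted p = 1.54e-06), but not with an estimated correlation (adjusted p = 0.223), with 22 of 26 higher and a median log2 ratio of 0.35. The genes of DNA replication and G1/S fell as a group by camera (adjusted p = 0.0019), but not with an estimated correlation (adjusted p = 0.532), without docetaxel replicate 2 (0.119) or on Cy5 arrays alone (0.161). Of 35 members 26 were lower, with a median of -0.26. The heat shock proteins, chaperones that assist protein folding, were higher in 16 of 20 members, with a median of 0.09 (camera adjusted p = 0.0311, with an estimated correlation adjusted p = 0.482). The estimated correlation was 0.0192 for the p53 targets, 0.0535 for the replication genes and -0.000539 for the heat shock proteins. The last lies below the preset 0.01, so its lost call does not come from a higher correlation. The unadjusted camera p of the heat shock proteins still rose from 0.0031 with the preset to 0.0321 with the estimate. The settings therefore differ in more than the size of the correlation. Whether higher correlations account for the lost calls of the p53 targets and the replication genes was not tested. CDKN1A stood at 1.32 ± 0.11 (SD, n = 3), 2.50-fold, above 0 on 6 of 6 arrays, and TNFRSF10B, the death receptor DR5, at 0.66 ± 0.16 (SD, n = 3). DDB2 stood at 0.47 ± 0.02 (SD, n = 3), with single arrays between 0.12 and 0.77. The replication genes included POLA1, the catalytic subunit of DNA polymerase alpha, at -0.70 ± 0.12, and MCM4, a helicase subunit, at -1.01 ± 0.46 (SD, n = 3). HSPB8, a small heat shock protein, stood at 2.01 ± 1.12, and HSPA6, an inducible member of the HSP70 family, at 0.83 ± 0.46 (SD, n = 3), with means of 1.58 on Cy3 and 0.08 on Cy5 arrays.

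Over all alternatives the adjusted p with docetaxel ranged from 1.41e-06 to 0.92 for the p53 targets, from 0.00014 to 0.92 for the replication genes and from 0.0329 to 0.92 for the heat shock proteins. The heat shock call was lost without docetaxel replicate 1 (camera adjusted p = 0.285), without docetaxel replicate 2 (0.119), on arrays of either dye orientation alone (0.184 and 0.404), with camera on ranks (0.061), and with only genes above the lowest value on all 12 arrays (0.0584). The p53 targets stood at 0.41 ± 0.08 on Cy3 arrays and 0.38 ± 0.03 on Cy5 arrays, the replication genes at -0.33 ± 0.18 and -0.13 ± 0.07, and the heat shock proteins at 0.09 ± 0.03 and 0.15 ± 0.09 (means of array medians, SD, n = 3). Of the p53 targets 0 passed over all genes and 1, CDKN1A, passed when adjusted over the list alone. No replication gene and no heat shock gene passed over all genes or adjusted over the list alone. The G2/M and mitosis genes had a median of -0.10, with 26 of 37 lower (camera adjusted p = 0.294). Of these 0 passed over all genes and 1 passed when adjusted over the list alone, MAD2L1, a spindle checkpoint protein named after its values were seen, at -1.38 ± 0.45 (SD, n = 3). The tubulins had a median of -0.02 over 12 members (camera adjusted p = 0.967). In fry's test for changes in either direction the tubulins did not pass (adjusted p = 0.467). The G2/M and mitosis genes passed it (adjusted p = 0.0013), as did other lists. Markers of other cell types had a median of -0.12 for leukocytes (camera adjusted p = 0.94) and 0.000575 for fibroblast and stromal cells (camera adjusted p = 0.92).

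One feature of 18900 passed the limma test for docetaxel, a probe without a listed gene, 7.1.16.10, at -6.64 (adjusted p = 0.00577). Of its 6 docetaxel arrays 3 were at the lowest ratio and 3 had no value, so its size is set by that limit. At an unadjusted p under 0.05 there were 1909 features, where chance gives 945. An unmoderated t statistic called 3, and the fit to single arrays called 9 features, among them CDKN1A (adjusted p = 0.00639), STRN4, ASPHD2, SPRY2 and S100P. The last 3, named after their values were seen, stood at -1.05, -1.01 and -0.94. In the limma fit to replicates CDKN1A had an adjusted p of 0.218. With only genes above the lowest value on all 12 arrays, a setting chosen after seeing the data, the fit to single arrays called 77, 25 higher and 52 lower. The named genes with the smallest p among those that were higher were ACSM1, an acyl-CoA synthetase, at 1.02 ± 0.10, SCAF11 at 1.12 ± 0.17, MIR155HG, the host transcript of miR-155, at 1.68 ± 0.45, CDKN1A, and DIS3, an exosome ribonuclease, at 1.45 ± 0.40 (SD, n = 3). MIR155HG rests mostly on Cy3 arrays: 2 of its 3 Cy5 values are missing, and its means were 2.12 on Cy3 and 0.14 on Cy5 arrays. The means of DIS3 were 0.48 and 2.42, those of CDKN1A 1.51 and 1.13, and those of SCAF11 1.22 and 1.01. Among those that were lower, ME3, a mitochondrial malic enzyme, stood at -1.87 ± 0.09, STRN4 at -1.81 ± 0.23 and NRG2, a neuregulin, at -1.57 ± 0.23 (SD, n = 3). With the signs of the Cy5 arrays turned, ACSM1 stood at -0.40, SCAF11 at 0.10, MIR155HG at 1.63, CDKN1A at 0.19, DIS3 at -0.97, ME3 at 0.25, STRN4 at -0.91 and NRG2 at 1.18. For NRG2, replicates 1 and 2 rest on the Cy5 array alone. The means on Cy3 and Cy5 arrays were -2.43 and -1.48 for ME3 and -2.72 and -0.90 for STRN4. GREB1 stood at -1.65 and TCAM1P at -6.64, and both rest on values at the lowest ratio. With such values set to missing GREB1 stood at 0.05. With the signs of the Cy5 arrays turned GREB1 stood at -0.56 and TCAM1P at 2.215.

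**Figure D1:**
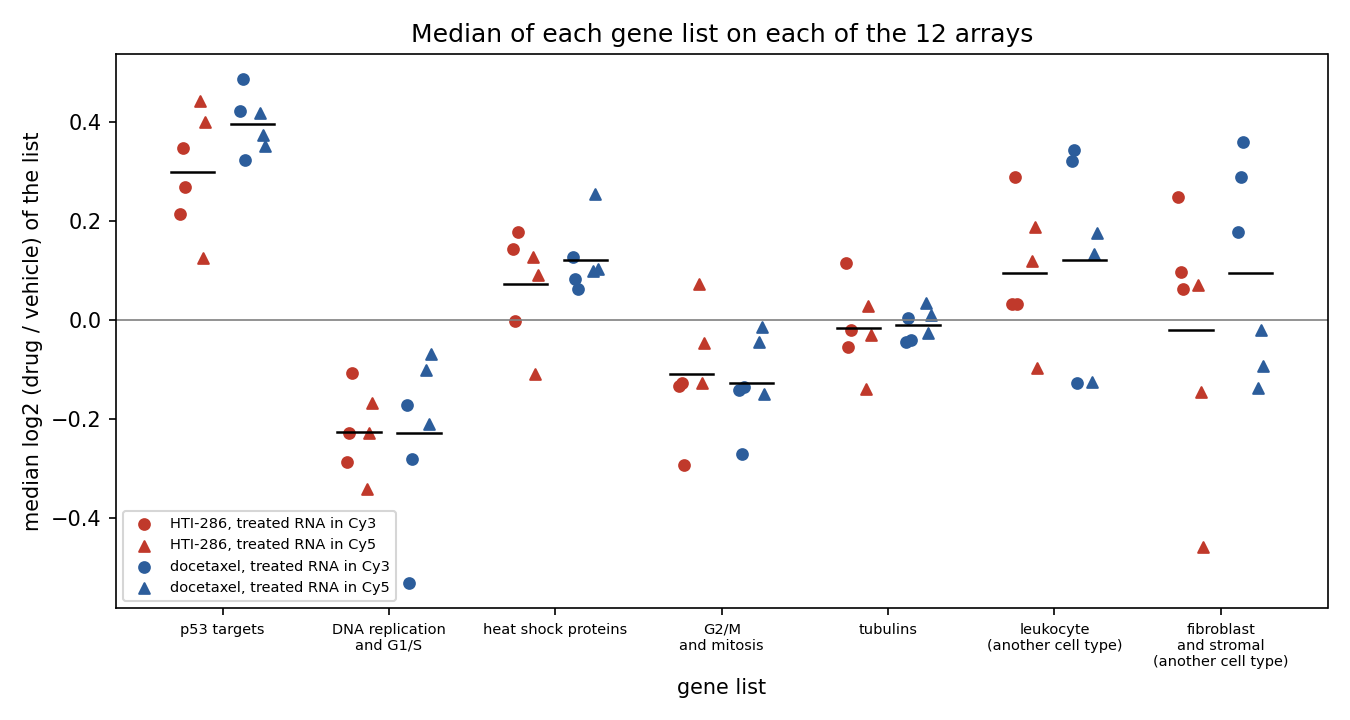
Median log2 ratio of drug over vehicle of 7 gene lists (x axis) on each of the 12 arrays (y axis, log2), with circles for arrays with the treated RNA in Cy3, triangles for Cy5, and a bar at the mean of the 6 array medians of each drug. The p53 targets lie above 0 and the DNA replication genes below 0 on 12 of 12 arrays.

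The third comparison asked where the responses to the drugs differed. The doses differed, 0.75 nM of HTI-286 and 3 nM of docetaxel, so the values stand side by side without a matched dose. CDKN1A and CLU were close in both: the difference, HTI-286 minus docetaxel, was -0.16 for CDKN1A (95% interval -0.73 to 0.40) and 0.03 for CLU (-0.49 to 0.54). FEN1 stood at -0.76 with HTI-286 and -0.06 with docetaxel, a difference of -0.70 (95% interval -1.20 to -0.21). POLA1 stood at -0.03 and -0.70, a difference of 0.67 (0.25 to 1.09). MCM6 stood at -1.23 and -0.32, MCM4 at -0.38 and -1.01, and ME3 at -0.75 and -1.87. None of these genes passed over all genes tested (limma adjusted p = 0.862 for FEN1, 0.817 for POLA1 and 0.706 for ME3), and the intervals are not adjusted for the number of genes. FEN1 and MCM6 were named for their small p with HTI-286, and POLA1, MCM4 and ME3 for theirs with docetaxel, which favours a difference between the drugs, so these intervals are descriptive. They also rest on the ratios as deposited. With the signs of the Cy5 arrays turned, FEN1 stood at 0.08 with HTI-286 and 0.24 with docetaxel, and POLA1 at 0.11 and -0.11. MCM6 then stood at -0.07 and -0.18, and MCM4 at -0.33 and -0.63.

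Of 18900 features 1 passed the limma test of the difference, the unnamed probe 7.1.16.10 (7.27, adjusted p = 0.0238), and 1045 had an unadjusted p under 0.05. None of 30 gene lists differed between the drugs by camera, or by fry in one direction. In fry's test for changes in either direction 1 passed, the replication genes (adjusted p = 0.000129). The median difference was -0.12 for the p53 targets (camera adjusted p = 0.884), -0.02 for the replication genes (0.928) and -0.08 for the heat shock proteins (0.884). A p that misses the threshold does not show that the drugs act alike.

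A set of genes fixed in advance for microtubules, the cell cycle, the prostate and drug resistance was measured with both drugs. With HTI-286, TUBB3 stood at 0.14 ± 0.14, TUBB2A at 0.02 ± 0.15, and STMN1, which destabilises microtubules, at 0.13 ± 0.26 (SD, n = 3). With docetaxel these were 0.00358 ± 0.13, 0.03 ± 0.40 and 0.16 ± 0.13. The mitotic genes CCNB1 and TOP2A stood at 0.00366 ± 0.07 and -0.00985 ± 0.64 with HTI-286 and at -0.12 ± 0.36 and -0.11 ± 0.34 with docetaxel. KLK3, which encodes prostate-specific antigen, stood at -0.40 ± 0.25 and -0.26 ± 0.41. MDM2 stood at -0.10 ± 0.64 and 0.25 ± 0.14, and GDF15 at 0.47 ± 0.66 and 0.59 ± 0.28. The efflux pump gene ABCB1 stood at -0.12 ± 0.63 and 1.19 ± 0.88, BCL2 at 0.72 ± 0.30 and -1.40 ± 1.90, the chaperone gene HSPA5 at 0.12 ± 0.27 and -0.06 ± 0.17, and CHGA at 0.52 ± 0.28 and 0.06 ± 0.42. By orientation, with HTI-286 the means on Cy3 and Cy5 arrays were 1.38 and -0.43 for GDF15, 1.81 and -0.36 for BCL2, and 0.36 and -0.60 for ABCB1. With docetaxel they were 0.13 and 1.05 for GDF15, -1.66 and -1.13 for BCL2, and 1.57 and 1.24 for ABCB1, whose replicate 2 rests on the Cy5 array alone. With the signs of the Cy5 arrays turned, ABCB1 stood at 0.48 with HTI-286 and -0.14 with docetaxel, BCL2 at 1.08 and -0.27, and GDF15 at 0.91 and -0.46. With the ratios as deposited, none of the fixed genes passed the limma test for either drug over all genes.

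**Figure D2:**
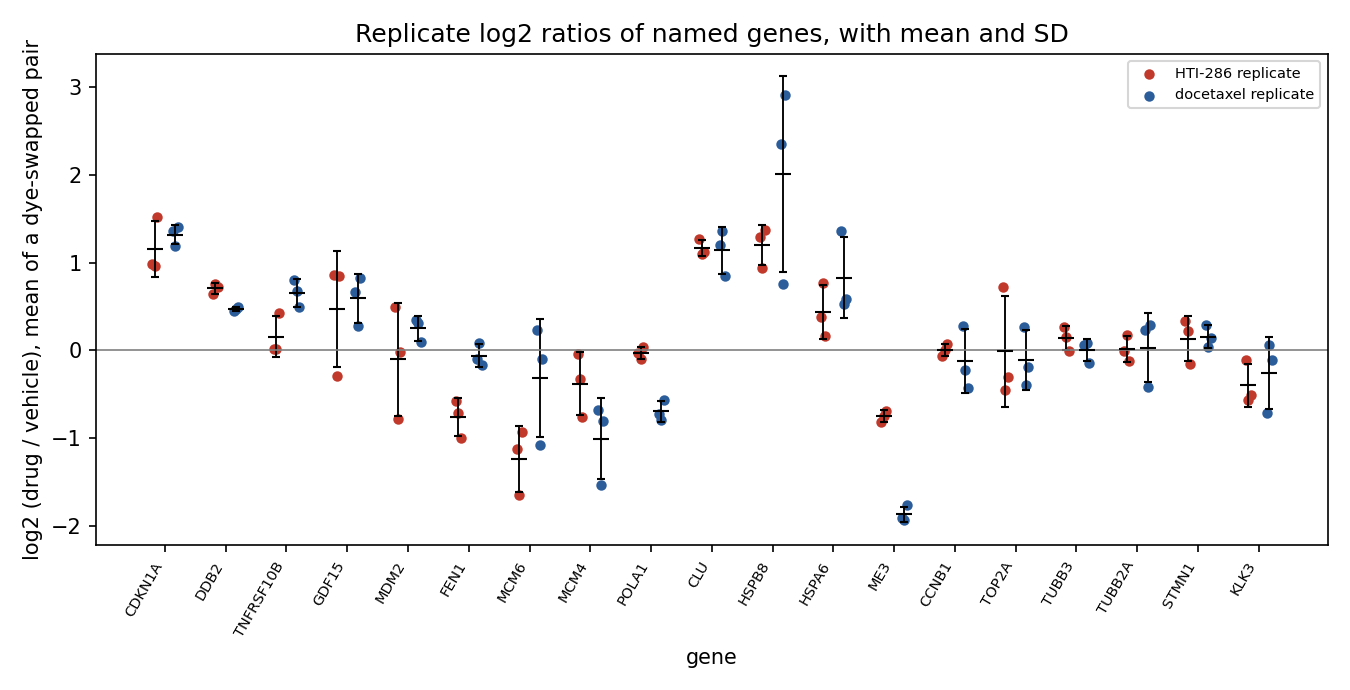
Log2 ratio of drug over vehicle (y axis) of 19 named genes (x axis) in each replicate, a point being the mean of a dye-exchanged pair, with the mean and SD of 3 replicates per drug. CDKN1A lies above 0 in every replicate of both drugs, and TUBB2A and CCNB1 spread around 0.

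The rule in the submitters' design, over 1.5-fold in the same direction in 3 of 3 replicates, picked 262 features for HTI-286, 157 higher and 105 lower. It picked 496 for docetaxel, 235 higher and 261 lower. If replicates were independent and every feature were equally likely to pass, 66.3 and 146 would be picked. Features with a wide spread pass more often, so counts above these values are not by themselves a drug response. The numbers given below for independent lists have the same limit. Between the drugs 9 were shared as higher, where independent lists would share 1.95, 8 as lower, where they would share 1.45, and 9 were opposite, where they would share 3.47. With the signs of the Cy5 arrays turned, 47 were shared as higher, where independent lists would share 7.54, 5 as lower (2.15) and 7 were opposite (8.12), so these counts depend on the unsettled direction. The shared higher genes included CDKN1A, CLU, HSPB8 and TRPC5, and the shared lower genes included ME3. On all 6 arrays, 18 features met 1.5-fold for each drug, and CDKN1A was the only 1 in both. With the signs of the Cy5 arrays turned CDKN1A stood at 0.21 with HTI-286 and 0.19 with docetaxel and would not qualify, so this too depends on that direction. Across 18900 genes the mean log2 ratios of the drugs correlated at r = 0.0716 and rho = 0.0931, and genes are not independent replicates. Within 1 dye orientation r was 0.11 (Cy3) and 0.16 (Cy5), and across orientations it turned to -0.0672 and -0.0379.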

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

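In this part the test on olfactory receptor genes was set out before its result was seen, and every other test was chosen or worded after the result it bears on had been seen.

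The p53 targets were higher and the replication genes lower with both drugs, on 12 of 12 arrays for each list. With only genes above the lowest ratio on all 12 arrays, 4 of 4 calls passed by camera with the preset correlation. That filter kept 24 of 26 p53 targets and 32 of 35 replication genes. Values at the lowest ratio are therefore argued against as the cause. Dim probes above that ratio stay open, since no brightness was used. Of 32 sign patterns of the replicates, for the average of both drugs, 1, the real one and the fewest this design allows, gave a camera p as small for the p53 targets (2.8e-11, next 2.59e-09), and 1 for the replication genes (3.57e-08, next 1.02e-06). These lists were the most extreme of 30, and in an exact sign-flip test of list medians 8 lists reached its smallest possible two-sided p of 0.0312 (adjusted p = 0.117), so chance stays open once all lists are counted. Also open is dye bias, which could give 1 sign on 12 of 12 arrays if the dye-exchanged ratios were deposited without turning. The medians of 41 olfactory receptor genes, which should not respond, turned sign with the dye beyond the SD for 0 of 2 drugs: with docetaxel they kept 1 sign beyond the SD on Cy3 and Cy5 arrays (-0.17 ± 0.15 and -0.23 ± 0.06), as unturned ratios would, and with HTI-286 they lay within the SD (0.12 ± 0.13 and -0.09 ± 0.09), so turned and unturned ratios cannot be told apart, and a drug response remains a hypothesis.

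The array of HTI-286 replicate 1 with the treated RNA in Cy5 had 1143 missing values, far from the other 5 arrays of that drug. The heat shock proteins had a median of 0.26 on the array of docetaxel replicate 2 with the treated RNA in Cy5, far above the other 5. Of 12 groups of arrays tested in this way 2 stood out, and chance marks about 1 in 20 groups. The unnamed probe 7.1.16.10 differed between the drugs by 7.27 (limma adjusted p = 0.0238), with 3 docetaxel arrays at the lowest ratio and 3 missing.

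For the counts of genes there are too few regroupings for a share under 0.05. For HTI-286 4 of 4 sign patterns gave as many as the real 0, and the highest other was 0. For docetaxel 1 of 4 did, with 1 gene against a highest other of 0, and for the difference 1 of 10 splits did, with 1 against 0.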

How the results depend on the processing

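Tests with lowest values set to missing, with only genes above the lowest value on all 12 arrays, alone or with the fit to all arrays, on ranks, and with the signs of dye-exchanged arrays turned were chosen after seeing the data. The cause of a change was not tested unless the alternative's own construction shows it. No brightness was used here, so signal over background is unknown. A correlation over only the genes called for either drug could not be computed, since 1 was called.

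For HTI-286 the 0 genes became 1 with only genes whose dye-exchanged arrays share a sign (fewer tested), 1 in the fit to all arrays, 2 in that fit above the lowest value, 1 on Cy5 arrays, and 0 to 2 without 1 replicate (1 without HTI-286 replicate 1, 2 without HTI-286 replicate 3). The filter on shared signs selects on the values then tested, which favours small p for either drug. For docetaxel the 1 became 0 after scaling, with values on all 12 arrays, on Cy5 arrays, in a fit of that drug alone, above the lowest value and with signs turned. It became 2 with the looser filter and with lowest values missing, 3 by the unmoderated statistic, 18 with shared signs, 9 in the fit to all arrays, 77 in that fit above the lowest value, and 1 to 6 without 1 replicate (5 without docetaxel replicate 1, 6 without docetaxel replicate 2, 2 without HTI-286 replicate 3). For the difference the 1 became 0 after scaling, with values on all 12 arrays, with shared signs, on Cy3 or Cy5 arrays, with limited ratios, with lowest values missing, above the lowest value with or without the fit to all arrays, and with signs turned, and 0 to 4 without 1 replicate (4 without docetaxel replicate 2, 2 without HTI-286 replicate 1, and 0 without HTI-286 replicate 2, docetaxel replicate 1 or docetaxel replicate 3). With the replicate number as a block it became 0. The numbers do not pair the samples (correlations of deviations -0.0175, 0.00483 and 0.00811).

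The 262 features picked by the fold rule for HTI-286 became 18 on all 6 arrays, 55 at 2-fold, 491 on Cy3 arrays, 436 on Cy5 arrays, 80 above the lowest value, 485 with signs turned, and 886 to 1007 without 1 replicate, where 2 of 2 suffice. The 496 for docetaxel became 18, 131 at 2-fold, 824 on Cy3 arrays, 544 on Cy5 arrays, 694 with signs turned, 197 above the lowest value, and 1556 to 1593 without 1 replicate. The correlation of the drugs became 0.11 on Cy3 and 0.16 on Cy5 arrays, -0.0672 and -0.0379 across orientations, 0.128 above the lowest value, 0.172 with signs turned, and 0.0398 to 0.0773 without 1 replicate.

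Of 2 lists for HTI-286, 0 passed with an estimated correlation, by fry in 1 direction or with signs turned, and 2 without any 1 replicate. Of 3 for docetaxel, 0 passed with an estimated correlation, 1 by fry in 1 direction (p53 targets, 0.04997), 1 on Cy5 arrays, 0 with signs turned, and 1 to 3 without 1 replicate (1 without docetaxel replicate 2). In fry's test for changes in either direction these lists passed. With HTI-286 the adjusted p was 0.000215 for the p53 targets and 3.74e-05 for the replication genes. With docetaxel it was 0.000709, 0.00212 and, for the heat shock proteins, 0.00297. Other lists passed that test with each drug, so it does not single these out. With signs turned the medians became -0.0199 for p53 targets and 0.0021 for replication genes with HTI-286, and -0.0251 for heat shock proteins with docetaxel. Of 1224 alternative values of named genes 1162 kept their sign, 62 did not, and 18 passed 0.05. Some settings, such as robust eBayes and the unmoderated statistic, change p and not the value, so many signs were kept by construction. With signs turned, CLU, DDB2 and FEN1 with HTI-286 and ACSM1, DIS3, ME3 and NRG2 with docetaxel were among those that changed sign. CDKN1A kept its sign with both drugs.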

Other observations

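Apart from the correlation of the drugs and the list tests for each drug alone, the tests in this part were chosen after related results had been seen.

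Averaged over both drugs, 2 further groups were higher by camera: the androgen response genes (adjusted p = 0.0228, with an estimated correlation adjusted p = 0.328) and the lysosome and autophagy genes (adjusted p = 0.0228, with an estimated correlation adjusted p = 0.324). With HTI-286 alone, 19 of 29 androgen response genes and 21 of 28 lysosome and autophagy genes were higher, with medians of 0.08 and 0.15. With docetaxel alone, 19 of 29 and 18 of 28 were higher, with medians of 0.15 and 0.08. By orientation, the means of array medians on Cy3 and Cy5 arrays were -0.00924 ± 0.15 and 0.14 ± 0.05 for the androgen response genes with HTI-286, and 0.07 ± 0.12 and 0.17 ± 0.03 with docetaxel (SD, n = 3). For the lysosome and autophagy genes they were 0.13 ± 0.17 and 0.18 ± 0.05 with HTI-286, and 0.05 ± 0.13 and 0.26 ± 0.03 with docetaxel (SD, n = 3). Neither group passed camera for either drug alone, and 2 of 32 sign patterns of the replicates, the real one included, gave as many lists for the average (5, highest other 5). No gene passed limma for the average (0 of 18900, with 1741 at an unadjusted p under 0.05). The smallest adjusted p among named genes was that of ME3 (0.0708, log2 ratio -1.31).

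Arrays resembled each other more within a dye orientation than within a dye-exchanged pair. Arrays of 1 drug in the same orientation correlated at a mean r of 0.106 for HTI-286 and 0.115 for docetaxel across genes, and the 2 arrays of a dye-exchanged pair at -0.0468. A candidate explanation is dye bias shared by both drugs: the Cy3 minus Cy5 difference correlated between the drugs at 0.186, against at most 0.0536 in 9 mixed pairings. If the dye-exchanged ratios were not turned, a response shared by both drugs would read alike, so this does not separate the explanations. In the fit to all arrays the dye term called 14 features, and 35 with only genes above the lowest value on all 12 arrays.

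The correlation of the drugs across genes was low, at 0.0716. A candidate explanation is measurement noise: from the correlations between replicates, identical responses would correlate at 0.121. The observed value lies below that, and a real difference between the drugs stays open. In the 4725 genes with the smallest spread between replicates the values were 0.267 observed and 0.771 if identical, but choosing genes by that spread raises the latter by construction.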
